A study of Bos taurus with 17 samples.

How the data were processed

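RNA of bovine umbilical cord mesenchymal stem cells was measured by MARS-seq, a method that counts the 3′ ends of polyadenylated transcripts. The labels describe 17 libraries in 6 groups, and 15 libraries in 5 groups were used here. The names of 2 value columns matched no sample in the labels, so these columns entered no step and the scaffold group of day 0 was not analysed here. Total RNA was extracted with a PureLink kit and libraries were prepared at the Weizmann Institute, per the labels' protocols. Trimming, alignment, counting and scaling involved cutadapt, STAR, HTSeq and DESeq against the bovine build ARS-UCD1.2, per the submitters' processing notes, which give no versions. Whether reads were collapsed by molecular identifier and whether strand was used in counting is not given in the sources used here, so reads of overlapping or antisense genes could not be told apart.

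The deposited table holds a normalized signal for 12894 genes, which the authors made by dividing each library's read counts by 1 scaling factor per library. Dividing each library's values by the value of 1 read gave whole numbers for 100% of the values within a tolerance of 0.1, with a largest distance from a whole number of 5.03e-05. Size factors recomputed from these recovered reads were 0.996 to 1.004 times the deposited ones. Recovered reads per library ran from 2197356 to 15483745 with a median of 7510490, and 1 read was worth 0.395 to 3.44 normalized reads depending on the library. The table names no symbol for 1498 genes, of which the reference table (assembly ARS-UCD2.0, used for names alone) matched 0, and 33 symbols are held by more than 1 gene. No coordinates are printed, because the build of the reference differs from that of the reads.

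The deposited values were analysed as log2(value + 1) in limma 3.58.1 (R 4.3.3) with a mean-variance trend and robust variance estimation, in 1 fit of the 15 libraries with a mean per group. Fold changes are on this scale, which understates the change of genes with few reads. Genes with a mean value of at least 5 over the 15 libraries were tested, which kept 10960 genes and left out 1934. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05 with a log2 fold change of at least 1 in either direction. "Rose", "fell" and "changed" are used for called genes. The filter and the fit had been designed for 17 libraries. The planned comparisons with the scaffold cells of day 0 and the 2 interactions built on them were not run, and comparisons of each scaffold group with day 0 on plastic were added after the data had been seen.

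Before the data were examined, 37 gene lists were fixed, of which the 35 with at least 5 tested members were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists within each comparison. Counts of list members are out of the tested members, which were 12 of 22 myogenic regulators, 14 of 48 skeletal muscle contractile and 8 of 19 chondrocyte genes. Genes that are low elsewhere can reach the minimum mean through the group where they are high, which raises the share that rose there. The same test with the correlation estimated from the data is printed wherever it ends a call. The genes to be named were also fixed beforehand by rule: the 3 or 5 largest rises and falls per comparison among called genes whose libraries did not overlap between the groups, the 2 called members with the largest change of each list that passed camera or had at least 3 called members, and the landmarks DES, ACTA2, COL1A1 and MKI67 in every comparison. The planned landmarks MYOD1 and MYOG were not analysed here. They are not among the 12 tested myogenic regulators, so the counts for that list do not cover them. The rule named 226 genes in 522 gene and comparison pairs, from which the text takes examples. Where a group held 0 reads of a gene, the fold is a lower bound from a floor of 3 reads over the whole group. Where it held 1 to 3 reads, the ratio is given with its 95% exact counting interval for genes the rule named in that comparison.

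Tests on simulated reads for 10960 genes, of which 200 had been changed 3-fold or 6-fold, recovered 82% to 92% of the smaller and 92% to 98% of the larger changes over the 8 comparisons. Unchanged genes were called 1 to 37 times, most often in comparisons with the 2 plastic libraries of day 21, and 0 of 100 unchanged lists passed camera. The simulated genes varied independently of each other, so this does not show how often camera passes unchanged lists of correlated genes. Each gene was also given the same variability in every group. False calls from groups that vary more than the rest were therefore not simulated. Alternatives comprised pseudocounts of 0.5 and 4, no filter and a minimum mean of 20, rescaling to the same total, quantile normalization, a fit of the compared groups alone, array weights, the replicate number as a block, no fold minimum, leaving out each library, and count tests on the recovered reads with edgeR 4.0.16 and DESeq2 1.42.0. A covariate for the gradient described among the day 3 libraries and thinning of all libraries to 2197356 reads were added after the data had been seen. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6. The labels name no sequencing or library batch, and an effect of one that followed the groups was not tested.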

Results

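Bovine umbilical cord mesenchymal stem cells, primary stromal cells able to enter several connective tissue lineages, were profiled in a study of cellulose scaffolds for cultivated meat. Cells on plastic were taken at day 0, the day after seeding (3 libraries), and after 3 days (3 libraries) and 21 days (2 libraries) in a myogenic differentiation medium with low serum, dexamethasone, ascorbate-2-phosphate, VEGF, IGF and FGF. Cells on scaffolds were taken at day 21, either with these growth factors in the medium (media scaffold, 4 libraries) or with the factors attached to the scaffold and left out of the medium (smart scaffold, 3 libraries). Recovered reads per library ranged from 8952711 to 15483745 at day 0, from 3118284 to 8629658 at day 3, from 2197356 to 5264578 on plastic at day 21, from 7397661 to 8975051 on the media scaffold and from 4315324 to 8258530 on the smart scaffold. The series' design text calls the libraries of a group biological replicates, and p-values rest on the spread between them, pooled over the 5 groups. For groups that vary more than the rest they can be too small. The lowest replicate correlations were those of plastic at day 21 (0.962) and of replicates 2 and 3 of day 3 (0.963). Intervals and floors of read counts cover counting error only. Values below are means ± SD of normalized reads over the n libraries of the group.

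Replicates correlated at 0.962 to 0.992 across genes, and every pair differed by more than counting noise (chi-square per degree of freedom 2.51 to 18.9). The first principal component held 53.6% of the variance and separated the scaffold libraries, at 57.2 to 65.3, from the plastic libraries of day 0 and day 3, at −84.5 to −64.0. The second held 27.8% and set apart the plastic libraries of day 21, at 102 and 126, while all others lay at or below 20.4. The 3 libraries of day 3 were spread along a gradient of their own, with scores of 1.57, 0.0068 and −1.90 for replicates 2, 1 and 3 in SD units over all libraries. Both plastic libraries of day 21 scored high on it, at 1.68 and 1.89, and all other libraries scored between −0.66 and −0.05.

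**Figure D1:**
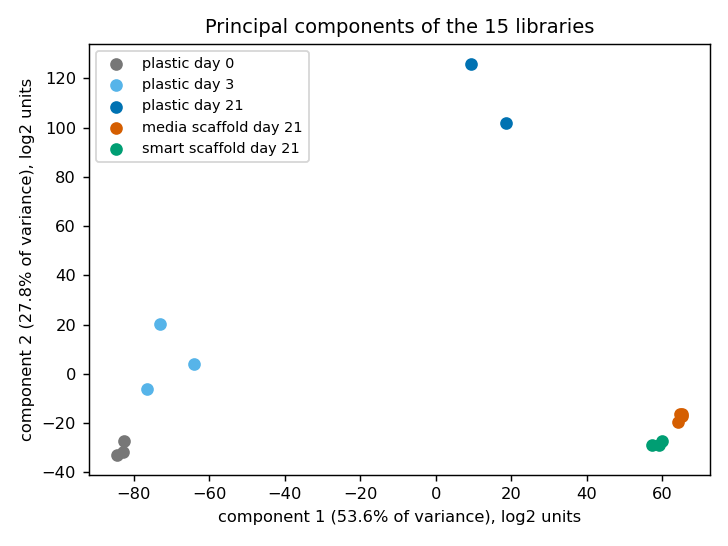
Principal component scores of the 15 libraries from log2 normalized values, with component 1 (53.6% of the variance) on the x axis and component 2 (27.8%) on the y axis, 1 point per library and 1 colour per group. The plastic libraries of day 21 lie alone at 102 and 126 on component 2, and both scaffold groups lie together at 57.2 to 65.3 on component 1.

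The first comparison addressed the first 3 days in differentiation medium on plastic, over which time in culture and medium changed together. Genes of cholesterol synthesis rose together by day 3: 22 of 23 members rose and 0 fell, with a median log2 change of 1.92 (camera adjusted p = 3.2e-28, and adjusted p = 0.00027 with an estimated correlation). TM7SF2, a sterol reductase, went from 7.04 ± 1.25 to 204 ± 70.8 (n = 3 and 3), and HMGCS1, which makes HMG-CoA, from 380 ± 60.9 to 4753 ± 478. Lipid handling genes on the adipocyte list moved the same way, with 5 of 15 members higher and 0 lower, among them the fatty acid desaturase SCD (log2 change 3.23) and the fatty acid binding protein FABP3 (2.80). The list's adjusted p was 0.00058, and adjusted p = 0.19 with an estimated correlation. ACSS2, which makes acetyl-CoA from acetate, was among the largest rises at 503 ± 155 against 12.5 ± 1.52 (log2 change 5.19, limma, Benjamini-Hochberg adjusted p = 3.26e-12), as were PLCD4 (4.66) and the tachykinin gene TAC3 (4.64).

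Genes of the amino acid response, which ATF4 drives when amino acids run short, fell at day 3 in 14 of 24 cases and rose in 1 (median −1.13, camera adjusted p = 2.6e-14, and adjusted p = 0.0018 with an estimated correlation). STC2, a secreted glycoprotein on that list and on the hypoxia and IGF axis lists, dropped from 242 ± 2.08 to 6.68 ± 2.95, and CHAC1, which degrades glutathione, from 277 ± 10.5 to 36.6 ± 13.2. DNA replication genes fell in 10 of 31 cases (median −0.84, adjusted p = 1.4e-11, and adjusted p = 0.0083 with an estimated correlation), a count of 6 without the second day 3 library. The licensing factor CDC6 fell by 2.73 on the log2 scale. Cell division genes fell in 6 of 34 cases and hypoxia genes in 10 of 25, with 2 higher (adjusted p = 5.9e-09 and 1.4e-06, each with adjusted p = 0.1 with an estimated correlation). The proliferation marker MKI67 stood at 1605 ± 230 and 952 ± 193, below the fold threshold (log2 change −0.76). YAP and TAZ targets, read out when cells spread and pull on their substrate, fell in 6 of 19 cases and rose in 0 (adjusted p = 0.0019, and adjusted p = 0.1 with an estimated correlation), led by ANKRD1, which went from 1144 ± 45 to 45.9 ± 7.04. The early growth response gene EGR1 went from 674 ± 44.2 to 112 ± 21.6.

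Dexamethasone is a glucocorticoid, but its part was not tested apart from time and the rest of the medium. Of 19 glucocorticoid targets, 8 rose at day 3 and 1 fell (adjusted p = 0.0089, and adjusted p = 0.19 with an estimated correlation). The clock gene PER1 rose from 63.1 ± 5.6 to 552 ± 104 and the chaperone FKBP5 stood at 691 ± 28.9 at day 3. Feedback targets of FGF and ERK signalling rose in 6 of 18 cases and fell in 1 (median 0.80, adjusted p = 0.028, and adjusted p = 0.1 with an estimated correlation), with SPRY2, an inhibitor of that pathway, going from 68.8 ± 6.39 to 292 ± 38.3. This list's adjusted p was 0.089 without replicate 3 of day 3. Other changed genes were the collagen prolyl hydroxylase P4HA3 (log2 change 4.27), the chemokine CCL2 (4.50), osteopontin SPP1 (1.35) and the glutathione peroxidase GPX1 (2.29). P4HA3 was the 1 of 21 collagen processing genes that rose, while 5 fell, among them LOXL4 (−2.06). The muscle intermediate filament DES stood at 993 ± 48.6 and 1351 ± 428 (log2 change 0.39, limma, Benjamini-Hochberg adjusted p = 0.0812). ACTA2, smooth muscle actin, and COL1A1, a chain of type I collagen, stayed below the fold threshold at −0.94 and −0.50.

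At day 3, 1096 of the 10960 genes tested were called, 687 higher and 409 lower, by limma with Benjamini-Hochberg adjustment. Adjusted over the list alone, the counts printed with a list's adjusted p for this comparison were the same, except that 7 cell division genes and 11 hypoxia genes fell and 7 FGF and ERK targets rose. The libraries of the groups did not overlap for 44.3% of genes, where chance gives 10%. For every gene called a change in the text, in this and the later comparisons, the libraries of the compared groups did not overlap.

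The second comparison addressed the outcome of 21 days on plastic. Proliferation genes were lower throughout: 34 of 34 cell division genes and 31 of 31 DNA replication genes fell against day 0, with medians of −4 and −2.89 (camera adjusted p = 2e-15 and 6.4e-13, and adjusted p = 0.059 and 0.015 with an estimated correlation). MKI67 went from 1605 ± 230 (n = 3) to 22.04 ± 2.01 (n = 2), and the replication-linked methylation regulator UHRF1 from 1019 ± 29.6 to 15.9 ± 12.7. The origin recognition gene ORC1 had 1 read on plastic at day 21 and 694 at day 0, a ratio of 121 (counting interval 21.6 to 4780).

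Extracellular matrix genes rose in 20 of 33 cases and fell in 3 (median 1.62, adjusted p = 1e-05, and adjusted p = 0.059 with an estimated correlation). Elastin, ELN, went from 19.0 ± 2.5 to 5842 ± 1120, and the microfibril gene MFAP5 from 15.4 ± 4.49 to 2723 ± 250. Basement membrane genes rose in 11 of 15 cases and fell in 0 (median 1.80, adjusted p = 2.3e-05, and adjusted p = 0.059 with an estimated correlation), among them the laminin chain LAMA4 (log2 change 4.21) and COL18A1 (4.25). COL1A1 stood at 46340 ± 1320 and 86800 ± 18900, a log2 change of 0.89 below the fold threshold, and at 1.11 without the first plastic library of day 21. Of 21 collagen processing genes, 10 rose and 4 fell, and P4HA3 changed most, at 18.2 ± 1.12 and 2618 ± 39.2.

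Smooth muscle and myofibroblast genes rose in 11 of 19 cases and fell in 2 (median 1.17, adjusted p = 0.00041, and adjusted p = 0.23 with an estimated correlation). Smooth muscle myosin MYH11 went from 19.8 ± 1.79 to 2469 ± 231. Its transcriptional coactivator MYOCD fell, with 276 reads at day 0 and 3 on plastic at day 21, a ratio of 16.0 (counting interval 5.43 to 78.2). ACTA2 rose from 27770 ± 2160 to 58560 ± 1070 (log2 change 1.08), a call that ended with rescaling to the same total (0.81) or quantile normalization (0.52). DES rose from 993 ± 48.6 to 13070 ± 1740. The skeletal muscle contractile list, to which DES belongs, had 4 of 14 members higher and 4 lower (adjusted p = 0.94). Its largest rise was the fast troponin gene TNNT3, with 74 reads against 2 (ratio 212, counting interval 56.8 to 1790), and its largest fall was the actin-binding gene XIRP1 (ratio 18.5, counting interval 5.05 to 153). Of 12 myogenic regulators, 1 rose and 1 fell (adjusted p = 0.94), or 2 and 1 without replicate 2 of plastic at day 21. The medians of these last lists, 0.09 and 0.03, changed sign without the second plastic library of day 21 (−0.43 and −0.02).

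Complement genes showed the largest list median on plastic at day 21: 8 of 11 rose and 0 fell, with a median of 5.67, or 5.4 with members at 0 reads set to their bound (adjusted p = 7.2e-05, and adjusted p = 0.059 with an estimated correlation). The protease C1S went from 2.598 ± 1.42 to 1567 ± 471 and its inhibitor SERPING1 from 1.01 ± 0.988 to 830 ± 279. On the IGF axis, 8 of 15 members rose and 2 fell (adjusted p = 0.0074, and adjusted p = 0.1 with an estimated correlation), with the ligand IGF2 at 96.7 ± 0.358 and 6764 ± 348 and the binding protein IGFBP3 at 701 ± 5.05 and 62430 ± 2980. Interferon response genes rose in 14 of 24 cases and fell in 3 (adjusted p = 0.0071, and adjusted p = 0.23 with an estimated correlation), led by IFI27 at 2.09 ± 1.27 and 598 ± 62.6. Blood and immune cell markers rose beside the complement and interferon lists, in 3 of 6 cases with 0 lower (adjusted p = 0.159). Among them were the lipopolysaccharide co-receptor CD14, from 0.939 ± 0.561 to 60.9 ± 6.16, and LAPTM5, from 2.14 ± 1.5 to 24.4 ± 9.18. Glucocorticoid targets rose in 10 of 19 cases and fell in 2 (adjusted p = 0.017, adjusted p = 0.23 with an estimated correlation, and 0.051 without the first plastic library of day 21), led by the monoamine oxidase MAOA (log2 change 7.48). The surface marker THY1 rose from 401 ± 30.1 to 18120 ± 2320. Among genes with a symbol the largest fitted rises were the chitinase-like CHI3L1 (log2 change 9.51), MSMP (9.18), the plasma glutathione peroxidase GPX3 (8.95), the scavenger receptor SCARA5 (8.94) and PODN (8.88).

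Several lists of energy metabolism and stress responses had more lower than higher members on plastic at day 21. Oxidative stress and NRF2 targets went both ways, with 7 of 27 higher and 7 lower (adjusted p = 0.765). Hypoxia genes fell in 16 of 25 cases and rose in 3, glycolysis genes fell in 10 of 19 and rose in 1, and amino acid response genes fell in 14 of 24 and rose in 2. Their adjusted p were 0.0019, 0.0016 and 0.00096, and adjusted p = 0.25, 0.3 and 0.085 with an estimated correlation. The lactate transporter SLC16A3 went from 337 ± 37 to 5.84 ± 6.31. ER stress genes fell in 11 of 22 cases and rose in 1 (adjusted p = 0.0015, and adjusted p = 0.059 with an estimated correlation), with MANF at 3477 ± 213 and 728 ± 145. Nuclear genes of oxidative phosphorylation fell in 16 of 49 cases and rose in 0 (adjusted p = 0.0074, and adjusted p = 0.21 with an estimated correlation), led by cytochrome c, CYCS, at 294 ± 2.69 and 8.27 ± 1.97. The small heat shock gene HSPB7 went from 906 ± 87.8 to 8.61 ± 2.41. Among called genes with a symbol and libraries that did not overlap, it had the largest fitted fall on the log2(value + 1) scale (−6.58). That scale understates the change of genes with few reads such as ORC1.

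Against day 0, 4956 genes were called on plastic at day 21, 2320 higher and 2636 lower (limma, Benjamini-Hochberg). The counts printed with a list's adjusted p for this comparison were the same adjusted over the list alone. Libraries did not overlap for 79.7% of genes, where chance gives 20%. Rescaling to the same total moved the median of all genes by −0.258 and gave 1812 higher and 3276 lower genes. Both plastic libraries of day 21 lay at the high end of the day 3 gradient. Among the counts printed with a list's adjusted p, those that moved most with the gradient as a covariate were small ones: myogenic regulators rose in 2 cases, ER stress genes rose in 2, smooth muscle genes fell in 1 and interferon response genes fell in 1. Rescaling to the same total gave 5 lower matrix genes, and leaving out replicate 2 of plastic at day 21 gave 1 lower glucocorticoid target.

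**Figure D2:**
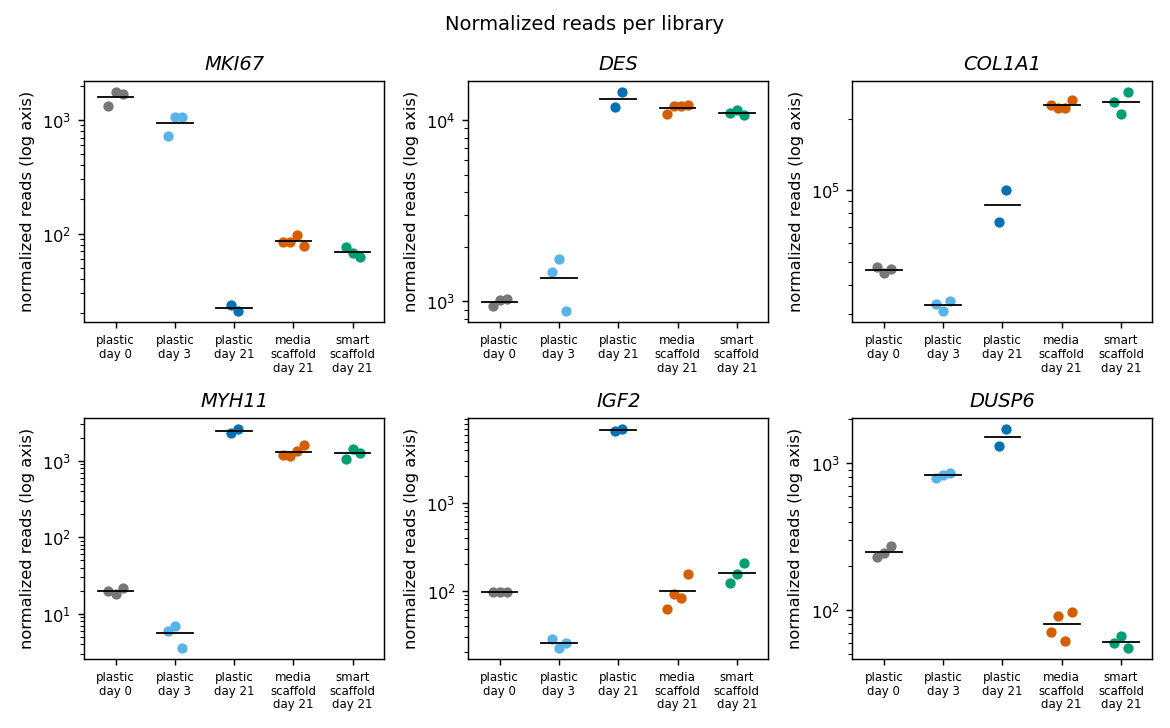
Normalized reads of 6 genes in each library, with the group on the x axis and a log y axis. Points are libraries and lines are group means. DES is at 11720 and 10980 on the scaffolds and 13070 on plastic at day 21, and MKI67 is below 100 in all 3 groups of day 21 and at 1605 at day 0.

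The later part of the plastic course was compared separately, from day 3 to day 21. Cholesterol synthesis genes fell in 18 of 23 cases and rose in 0 (median −1.41, camera adjusted p = 6.5e-09, and adjusted p = 0.019 with an estimated correlation), among them HSD17B7 and the squalene epoxidase SQLE, from 659 ± 286 (n = 3) to 95.1 ± 56.8 (n = 2). FABP3 fell from 2410 ± 589 to 68.2 ± 10.5 and SPP1 from 17360 ± 1790 to 826 ± 276. Matrix genes rose in 22 of 33 cases and fell in 1, basement membrane genes rose in 12 of 15 and fell in 0, and complement genes rose in 9 of 11 and fell in 0. These lists had adjusted p of 2.5e-09, 1.1e-06 and 4.3e-06, and adjusted p = 0.023, 0.023 and 0.032 with an estimated correlation. Blood and immune cell markers rose in 2 of 6 cases and fell in 0 (adjusted p = 0.342), with 1 higher when the gradient was a covariate or replicate 2 of plastic at day 21 was left out. Smooth muscle genes rose in 14 of 19 cases and fell in 1 (median 1.65, adjusted p = 3.8e-07, and adjusted p = 0.11 with an estimated correlation), with the myosin kinase MYLK at 2506 ± 209 and 31760 ± 8400. Cell division genes fell in 33 of 34 cases (median −3.10, adjusted p = 8.9e-16, and adjusted p = 0.032 with an estimated correlation). Hypoxia genes rose in 2 of 25 cases and fell in 8 (adjusted p = 0.266): the vasodilator peptide gene ADM rose from 1338 ± 91.7 to 25090 ± 2180, and the hexokinase HK2 fell, with 74 reads at day 3 and 1 at day 21 (ratio 24.7, counting interval 4.3 to 990). COL1A1, ACTA2 and DES rose by 1.39, 2.02 and 3.32 on the log2 scale. The cytokine IL36A, with 186 reads at day 3 and 0 at day 21, was at least 20.7-fold lower.

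From day 3 to day 21, 3824 genes were called, 1700 higher and 2124 lower (limma, Benjamini-Hochberg), and libraries did not overlap for 65.4% of genes, where chance gives 20%. Rescaling to the same total moved the median of all genes by −0.32 and gave 1148 higher and 3057 lower genes. Adjusted over the list alone, the counts named for this comparison were the same, except that 10 complement genes rose. The count of lower matrix genes was 3 after rescaling to the same total, and 0 with the gradient as a covariate or without replicate 2 of plastic at day 21. Rescaling also gave 1 higher hypoxia gene and 1 lower complement gene.

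Scaffold and plastic cultures were next compared at day 21. Feedback targets of FGF and ERK signalling were lower on both scaffolds: 12 of 18 fell and 2 rose on the media scaffold, and 11 fell and 2 rose on the smart scaffold (medians −1.60 and −1.64, camera adjusted p = 0.0043 and 0.0044, each with adjusted p = 0.11 with an estimated correlation). The ERK phosphatase DUSP6 stood at 1514 ± 289 on plastic (n = 2), 80.3 ± 16.7 on the media scaffold (n = 4) and 60.5 ± 5.89 on the smart scaffold (n = 3). IGF2 stood at 6764 ± 348, 98.1 ± 40.1 and 160 ± 41.5 in the same order. IGF axis genes fell in 7 of 15 cases and rose in 2 on the media scaffold (adjusted p = 0.0516), and fell in 9 and rose in 2 on the smart scaffold (adjusted p = 0.026, adjusted p = 0.25 with an estimated correlation and 0.051 after quantile normalization). IGF1 went against IGF2: it had 0 reads on plastic and 50.9 ± 11.6 on the media scaffold, at least 17-fold higher.

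Adipocyte genes rose in 10 of 15 cases and fell in 0 on each scaffold (medians 1.46 and 1.60). The list's adjusted p was 0.0043 on the media scaffold, adjusted p = 0.4 with an estimated correlation, and 0.062 on the smart scaffold. The lipid droplet gene CIDEC stood at 16.5 ± 3.94 on plastic, 642 ± 127 on the media scaffold and 325 ± 74.8 on the smart scaffold, and perilipin, PLIN1, at 22.1 ± 21.5, 323 ± 120 and 154 ± 52. Chondrocyte genes rose in 6 of 8 cases on each scaffold, with 0 lower on the media and 2 lower on the smart scaffold, where the counts were 5 higher and 1 lower without replicate 2 of plastic at day 21. The list's adjusted p was 0.0496 on the media scaffold, adjusted p = 0.27 with an estimated correlation and 0.052 with the day 3 gradient as a covariate, and 0.067 on the smart scaffold. COMP, a cartilage matrix gene, had 0 reads on plastic and was at least 22.9-fold and 38.3-fold higher on the media and smart scaffolds, and the link protein HAPLN1 rose from 5.52 ± 7.81 to 107 ± 6.49 and 87.8 ± 10.1.

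The matrix differed in both directions. COL1A1 rose from 86800 ± 18900 on plastic to 228200 ± 8450 and 235500 ± 24600 (log2 changes 1.41 and 1.45), calls that ended with quantile normalization (0.65 for each). Lumican, LUM, rose from 201 ± 69.7 to 4876 ± 110 and 5657 ± 1030, and the lysyl hydroxylase PLOD2 from 70.6 ± 12 to 979 ± 55.6 and 1264 ± 95.6. Of 33 matrix genes, 16 rose and 9 fell on the media scaffold and 15 rose and 9 fell on the smart scaffold (adjusted p = 0.23 and 0.47). Basement membrane genes fell in 6 of 15 cases on the media scaffold and 7 on the smart scaffold, with 3 higher on each (adjusted p = 0.097 and 0.067), and COL4A2 went from 2433 ± 72.4 to 267 ± 112 and 266 ± 189. Smooth muscle genes fell in 6 of 19 cases on the media scaffold (adjusted p = 0.0043, and adjusted p = 0.4 with an estimated correlation), a count of 3 without the second plastic library of day 21. On the smart scaffold 3 fell (adjusted p = 0.026, adjusted p = 0.47 with an estimated correlation, 0.059 without the same library and 0.051 after quantile normalization). The actin-binding gene CALD1 stood at 30460 ± 12900 on plastic, 9219 ± 583 on the media scaffold and 9377 ± 847 on the smart scaffold.

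Muscle genes split. Among 12 myogenic regulators, 6 rose and 1 fell on the media scaffold and 5 rose and 1 fell on the smart scaffold (adjusted p = 0.062 and 0.085, and 0.04 for the media scaffold without the second plastic library of day 21). EYA2, a transcriptional coactivator of muscle precursors, had 0 reads on plastic and was at least 86.0-fold and 71.4-fold higher, and the muscle laminin receptor ITGA7 rose from 132 ± 32.2 to 955 ± 79.9 and 1750 ± 143. ITGA7 had fallen on plastic from 1195 ± 123 at day 3 (log2 change −3.19), so its difference at day 21 includes that fall. Skeletal muscle contractile genes rose in 6 of 14 cases and fell in 2 on the media scaffold, and rose in 4 and fell in 2 on the smart scaffold (adjusted p = 0.34 and 0.51). The calcium store gene CASQ2 had 2 reads on plastic and 933 and 788 on the scaffolds (ratios 106 and 152, counting intervals 29.3 to 876 and 42.0 to 1260), while TNNT3 fell with ratios of 109 and 192 (counting intervals 35.7 to 539 and 33.3 to 7670). DES did not pass the test on either scaffold, at log2 changes of −0.15 and −0.25, and these turned to 0.38 and 0.36 with the gradient as a covariate (adjusted p = 0.00864 and 0.0209, limma, Benjamini-Hochberg), below the fold threshold. ACTA2 stood at −0.27 (adjusted p = 0.0418) and 0.18 (0.176, limma, Benjamini-Hochberg).

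Parts of the stress, energy and cell cycle lists were higher on the scaffolds than on plastic. No list call among them held with an estimated correlation. Glycolysis genes rose in 3 of 19 cases and fell in 0 on the media scaffold, and rose in 3 and fell in 2 on the smart scaffold (adjusted p = 0.189 and 0.599). Amino acid response genes rose in 8 of 24 cases and fell in 2 on the media scaffold, and rose in 9 and fell in 1 on the smart scaffold (adjusted p = 0.0043 and 0.0021, and adjusted p = 0.27 and 0.13 with an estimated correlation), with the pseudokinase TRIB3 at 17.2 ± 4.92 on plastic, 110 ± 6.45 and 167 ± 22.8. ER stress genes rose in 5 and 7 of 22 cases and fell in 0 (adjusted p = 0.0234 and 0.0044, and adjusted p = 0.27 and 0.13 with an estimated correlation). Oxidative phosphorylation genes rose in 10 and 12 of 49 cases and fell in 0 (adjusted p = 0.03 and 0.026, adjusted p = 0.4 and 0.41 with an estimated correlation, and 0.067 and 0.064 without the first plastic library of day 21), with CYCS at 8.27 ± 1.97, 90.8 ± 13.9 and 86.1 ± 29.1. DNA replication genes rose in 10 of 31 cases and fell in 0 on each scaffold (adjusted p = 0.041 and 0.062, and adjusted p = 0.4 with an estimated correlation for the media scaffold). Without the second plastic library of day 21 these counts were 5 and 6, and with the gradient as a covariate 5 and 4. MKI67 stood at 22.04 ± 2.01 on plastic, 85.8 ± 8.8 on the media scaffold and 68.3 ± 7.05 on the smart scaffold. Interferon response genes fell in 10 of 24 cases and rose in 1 on the media scaffold (adjusted p = 0.0496, adjusted p = 0.44 with an estimated correlation, 0.052 with the replicate number as a block, 0.1 without the first plastic library of day 21 and 0.051 without replicate 4 of the media scaffold), with IFI27 at 598 ± 62.6 on plastic and 12.95 ± 3.19. On the smart scaffold 9 fell and 1 rose (adjusted p = 0.0731, and 0.049 with the gradient as a covariate), with IFI27 at 9.99 ± 7.07. Blood and immune cell markers fell beside them, in 4 of 6 cases on the media and 5 on the smart scaffold with 0 higher (adjusted p = 0.0621 and 0.0616), counts that were 2 and 2 with the gradient as a covariate. CD14 stood at 60.9 ± 6.16 on plastic, 4.10 ± 1.42 on the media scaffold and 4.72 ± 1.16 on the smart scaffold.

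Among the largest rises over plastic were RSPO1, an activator of WNT signalling with 0 reads on plastic (at least 115-fold on the media and 95.6-fold on the smart scaffold), EYA2 on the media scaffold (at least 86.0-fold), and TSPAN13 (log2 change 7.84 on the media and 7.93 on the smart scaffold). MSMP went from 2801 ± 603 on plastic to 2.55 ± 1.75 on the media scaffold and had 0 reads on the smart scaffold, at least 2610-fold lower. The retinoic acid binding protein CRABP1 had 684 reads on plastic and 2 on each scaffold (ratios 1510 and 885, counting intervals 415 to 12500 and 244 to 7320). Against plastic, 3879 genes were called on the media scaffold, 2281 higher and 1598 lower, and 4109 on the smart scaffold, 2350 higher and 1759 lower (limma, Benjamini-Hochberg). Adjusted over the list alone, the counts named for these comparisons were the same. Libraries did not overlap for 71.2% and 73.1% of genes, where chance gives 13.3% and 20%. The plastic group has 2 libraries, which also scored highest on the day 3 gradient. Without its replicate 2, 0 myogenic regulators fell on either scaffold, 2 interferon response genes rose on each, and 1 amino acid response gene fell on the media scaffold. With the gradient as a covariate, 0 myogenic regulators, 1 amino acid response gene and 1 chondrocyte gene fell on the media scaffold, while 1 chondrocyte gene fell and 1 FGF and ERK target rose on the smart scaffold.

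**Figure D3:**
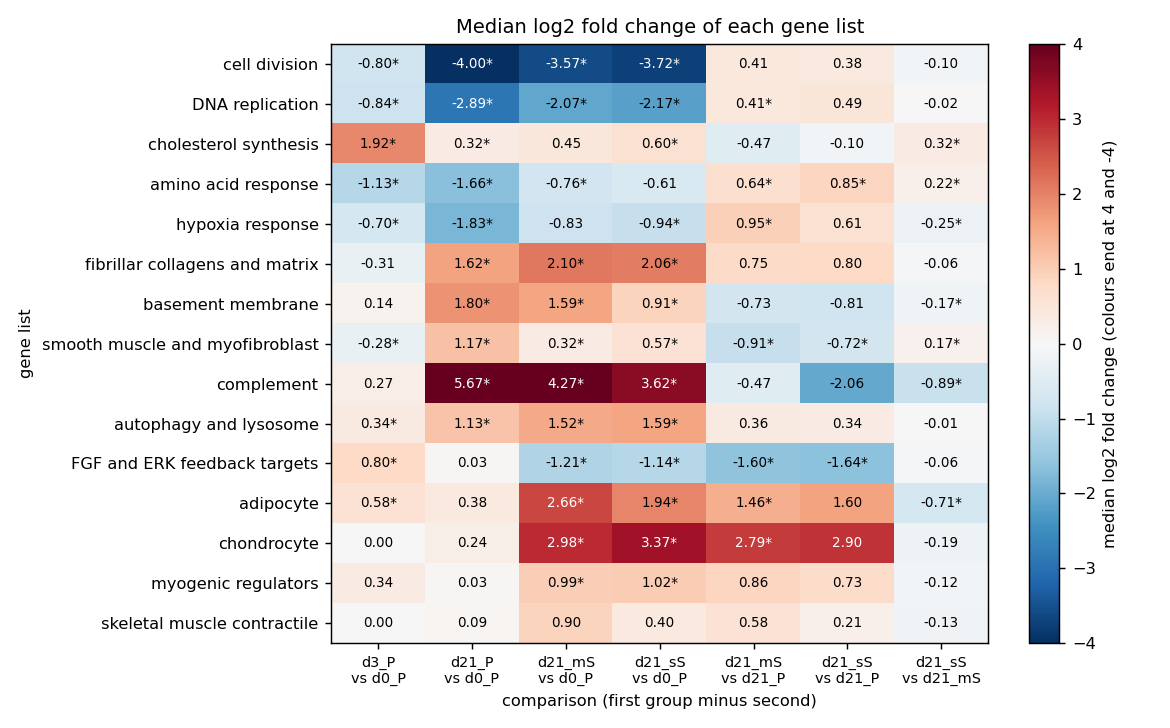
Median log2 fold change of 15 gene lists (y axis) in 7 comparisons (x axis), coloured and printed, with a star where camera with a preset correlation gave an adjusted p under 0.05. Cell division has medians of −4, −3.57 and −3.72 on plastic, media scaffold and smart scaffold at day 21 against day 0, and cholesterol synthesis has its highest median, 1.92, at day 3.

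The smart and media scaffolds were compared to ask what attaching the growth factors changed. Complement genes were lower on the smart scaffold: 2 of 11 fell and 0 rose, or 5 fell adjusted over the list alone (median −0.89, camera adjusted p = 1.4e-06, and adjusted p = 0.037 with an estimated correlation). SERPING1 stood at 58.0 ± 3.63 on the smart scaffold (n = 3) and 256 ± 76 on the media scaffold (n = 4), and C1S at 245 ± 41.9 and 736 ± 147. IGF axis genes fell in 3 of 15 cases, or 4 adjusted over the list alone, and rose in 0 (adjusted p = 0.00071, and adjusted p = 0.037 with an estimated correlation), with the binding protein IGFBP5 at 142 ± 52.4 and 320 ± 17. The IGFBP5 call ended without the second smart scaffold library (log2 change −0.98). Glucocorticoid targets fell in 2 of 19 cases by either adjustment and rose in 0 (adjusted p = 2.7e-05, and adjusted p = 0.037 with an estimated correlation), with the metallothionein MT2A at 43.8 ± 2.14 and 104 ± 12. Adipocyte genes fell in 1 of 15 cases, or 4 adjusted over the list alone (median −0.71, adjusted p = 0.00016, and adjusted p = 0.14 with an estimated correlation), and in 3 with the gradient as a covariate.

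Among genes with a symbol the largest fitted differences were the chemokine CXCL14, at 10.5 ± 2.39 on the smart and 208 ± 51.8 on the media scaffold (log2 change −4.17, limma, Benjamini-Hochberg adjusted p = 2.79e-06), SCARA5, at 110 ± 48.9 and 937 ± 156, and the protease inhibitor A2M, which had 0 reads on the smart scaffold and was at least 6.07-fold lower. LRRC17 stood at 1.80 ± 0.738 and 20.1 ± 3.19, and its call ended with thinning to the fewest reads. COX4I2 stood at 6.31 ± 1.84 and 57.2 ± 47.8, a mean that rests on replicate 4 of the media scaffold (128 against 26.3 to 40.5 in the others). Its log2 change went from −2.73 to −2.25 without that library, and its call ended without replicate 2 (adjusted p = 0.0533) or replicate 3 of the smart scaffold (0.0592, limma, Benjamini-Hochberg). The matrix gene FBLN1 stood at 54.7 ± 0.771 and 161 ± 30.2 (log2 change −1.52). The selenium carrier SELENOP stood at 481 ± 54.4 and 1242 ± 91, a call that ended without the second smart scaffold library (adjusted p = 0.0745).

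Few genes were higher on the smart scaffold. The small heat shock gene HSPB7 stood at 832 ± 76.4 against 386 ± 60.8 (log2 change 1.11). The calcium channel gene TRPC4 (log2 change 1.08) and the TGF beta target TGFBI (1.02) lay close to the fold threshold and lost their calls with a pseudocount of 4 (0.99 for each) or thinning to the fewest reads (0.93 and 0.99), and TGFBI also with array weights (0.99). Without the second media or the first smart scaffold library they stood at 0.90 and 0.98 for TRPC4 and at 0.98 and 0.98 for TGFBI, which also stood at 0.97 without the first media scaffold library. The levels of ISG20 were 5.70 ± 3.77 and 1.31 ± 0.752, and HPDL had 7 reads against 2 (ratio 5.95, counting interval 1.13 to 58.7). Both calls ended in both count tests (adjusted p = 0.107 in edgeR and 0.142 in DESeq2 for ISG20, 0.17 and 0.245 for HPDL). They also ended without single libraries of either scaffold, at adjusted p of 0.092 to 0.225 for ISG20 (replicates 1, 2 or 4 of the media, 1 or 3 of the smart scaffold) and 0.0645 to 0.156 for HPDL (replicates 2 or 4 of the media, 2 or 3 of the smart scaffold; limma, Benjamini-Hochberg). Of 15 TGF beta targets, 2 rose and 0 fell by either adjustment (adjusted p = 0.0027, and adjusted p = 0.037 with an estimated correlation). Cholesterol synthesis genes were shifted upward as a list (median 0.32, adjusted p = 1.9e-07, and adjusted p = 0.037 with an estimated correlation) with 0 of 23 members called by either adjustment. YAP and TAZ targets were shifted upward as well (median 0.22, adjusted p = 0.00024, and adjusted p = 0.037 with an estimated correlation), with 0 of 19 members called, or 1 adjusted over the list alone.

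No muscle or proliferation landmark reached the fold threshold between the scaffolds. DES stood at 10980 ± 316 on the smart and 11720 ± 584 on the media scaffold (log2 change −0.09, limma, Benjamini-Hochberg adjusted p = 0.874). MKI67 stood at 68.3 ± 7.05 and 85.8 ± 8.8 (−0.33), while ACTA2 stood at 66620 ± 6200 and 48920 ± 5340 (0.45, limma, Benjamini-Hochberg adjusted p = 0.0194, with libraries that did not overlap). COL1A1 stood at 235500 ± 24600 and 228200 ± 8450 (0.04, and −0.03 without replicate 3 of the smart scaffold). Of the myogenic, skeletal muscle contractile, cell division and DNA replication lists, 0 members were called by limma with either adjustment, and their camera adjusted p were 0.67, 0.8, 0.17 and 0.8.

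Between the scaffolds 99 genes were called, 8 higher and 91 lower on the smart scaffold (limma, Benjamini-Hochberg), and 107 and 104 by edgeR and DESeq2 on the recovered reads. Libraries did not overlap for 20.4% of genes, where chance gives 5.71%. The count moved to 192 with array weights and to 53 with all libraries thinned to the fewest reads. It moved to 61, 53 and 61 without replicates 1, 2 and 3 of the media scaffold and to 62 without replicate 2 of the smart scaffold.

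**Figure D4:**
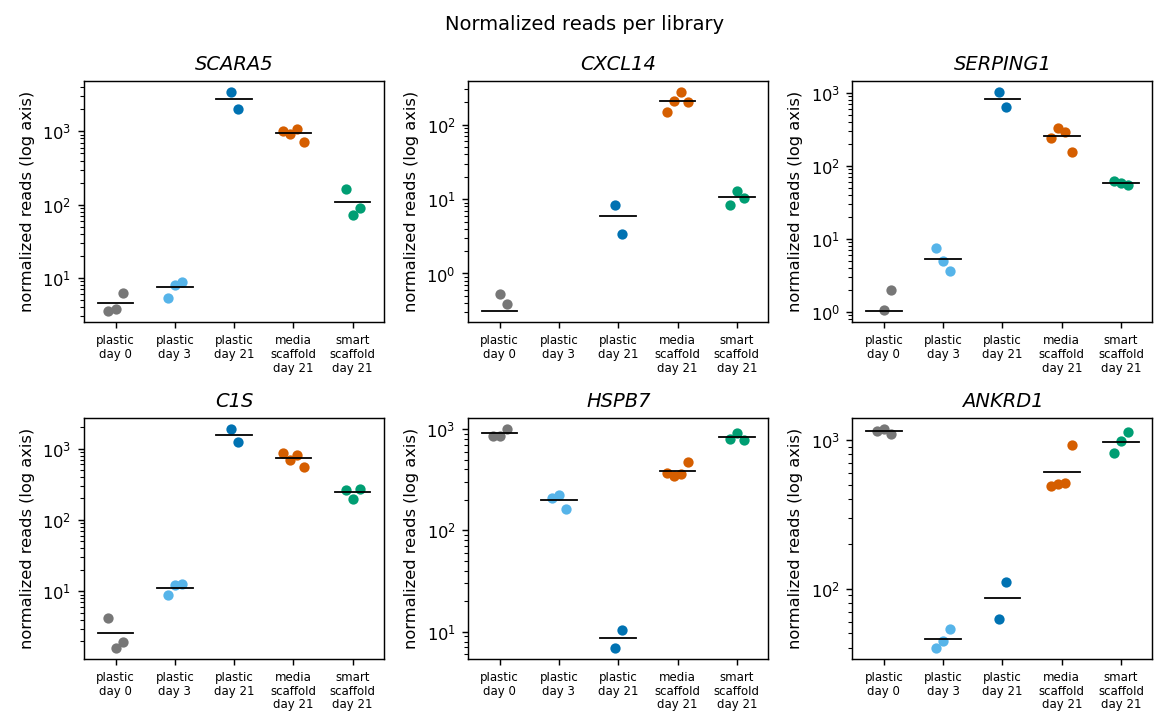
Normalized reads of 6 genes in each library, with the group on the x axis and a log y axis on which libraries with 0 reads are not drawn. Points are libraries and lines are group means. SCARA5, CXCL14, SERPING1 and C1S are lower on the smart than on the media scaffold, and HSPB7 is higher; ANKRD1, at 974 on the smart scaffold, was not called between the scaffolds.

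Finally, each scaffold group was compared with cells on plastic at day 0, which differ from it in time, medium and substrate together. Cell division genes fell in 34 of 34 cases on both scaffolds (medians −3.57 and −3.72, camera adjusted p = 3.8e-18 and 1.7e-19, and adjusted p = 0.032 and 0.026 with an estimated correlation), and MKI67 went from 1605 ± 230 (n = 3) to 85.8 ± 8.8 on the media scaffold (n = 4) and 68.3 ± 7.05 on the smart scaffold (n = 3). Matrix genes rose in 22 of 33 cases and fell in 2 on the media scaffold, and rose in 21 and fell in 1 on the smart scaffold (adjusted p = 1.9e-08 and 1.2e-08, and adjusted p = 0.032 and 0.026 with an estimated correlation). ELN went from 19.0 ± 2.5 to 26890 ± 3580 and 29110 ± 2470, the gelatinase MMP2 from 1065 ± 74.4 to 17570 ± 952 and 15160 ± 2050, and COL1A1 rose by 2.30 and 2.34 on the log2 scale. Complement genes rose in 9 of 11 cases and fell in 0 on each (medians 4.27 and 3.62, adjusted p = 3.2e-06 and 9.4e-06, and adjusted p = 0.032 and 0.028 with an estimated correlation). Lysosome and autophagy genes rose in 23 and 24 of 36 cases and fell in 1 on each (adjusted p = 2.3e-11 and 3.2e-12, and adjusted p = 0.032 and 0.028 with an estimated correlation), with the cathepsin CTSB at 702 ± 52.3 at day 0, 5626 ± 263 and 5409 ± 44.9. On plastic at day 21, 19 members of this list rose against day 0 and 5 fell.

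Chondrocyte genes rose in 7 of 8 cases and fell in 0 on each scaffold against day 0 (adjusted p = 0.0011 for each, and adjusted p = 0.032 and 0.028 with an estimated correlation), with the lubricin gene PRG4 at 1.29 ± 0.512, 1008 ± 162 and 648 ± 155. The list holds 19 genes, and members such as COMP were tested only because of their level on the scaffolds, which raises this share. Adipocyte genes rose in 10 and 11 of 15 cases and fell in 0 (adjusted p = 0.00035 and 0.0011, and adjusted p = 0.17 and 0.22 with an estimated correlation), with CIDEC at 3.65 ± 0.566, 642 ± 127 and 325 ± 74.8. Myogenic regulators rose in 5 and 6 of 12 cases and fell in 0 (adjusted p = 0.028 and 0.016, and adjusted p = 0.074 and 0.061 with an estimated correlation). The limb muscle homeobox gene MEOX2 went from 66.2 ± 6.8 to 276 ± 20.4 and 258 ± 25.3, and EYA2 was at least 494-fold and 410-fold higher than at day 0, where it had 0 reads. Skeletal muscle contractile genes rose in 4 and 5 of 14 cases and fell in 3 on each (adjusted p = 0.26 and 0.35), with DES at 993 ± 48.6, 11720 ± 584 and 10980 ± 316. FGF and ERK feedback targets fell in 11 and 9 of 18 cases and rose in 1 (adjusted p = 0.0056 and 0.0011, and adjusted p = 0.032 and 0.026 with an estimated correlation), with FOSL1 at 494 ± 49, 47.0 ± 8.55 and 49.7 ± 1.46. Glycolysis genes fell in 7 and 8 of 19 cases and rose in 1 on each (adjusted p = 0.00051 and 3.9e-05, and adjusted p = 0.27 and 0.21 with an estimated correlation), counts that were 11 and 13 after rescaling to the same total.

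PTX3, a secreted pattern recognition protein, had 3 reads at day 0 and 14123 and 11538 on the media and smart scaffolds (ratios 6140 and 8530, counting intervals 2100 to 29800 and 2920 to 41400). ACTA2 rose on the smart scaffold (log2 change 1.26, and 0.73 after quantile normalization, which ended the call) and stayed below the fold threshold on the media scaffold (0.81). Against day 0, 3548 genes were called on the media scaffold, 1913 higher and 1635 lower, and 3354 on the smart scaffold, 1808 higher and 1546 lower (limma, Benjamini-Hochberg). Adjusted over the list alone, the counts named for these comparisons were the same. Rescaling to the same total moved the median of all genes by −0.246 and −0.224 and gave 1494 higher and 2271 lower genes on the media scaffold and 1420 higher and 2155 lower on the smart scaffold, where 0 FGF and ERK targets rose and 1 myogenic regulator fell. Libraries did not overlap for 72.4% and 72.9% of genes, where chance gives 5.71% and 10%.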

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

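The tests of the day 3 gradient and of depth for the genes differing between media scaffold and plastic, the test of the gradient for the otherwise stable genes, and the share of lower genes among those called anew without each library, were chosen only after the result was seen.

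In the media scaffold group, the only one with 4 libraries, 230 values were examined for a library far from the other 3. They were those of named genes and a few library measures such as recovered reads. Of these, 23, all of genes, had a gap to the nearest library over Dixon's critical share of the group's range at 95%. Chance alone gives about 1 in 20. Replicate 4 lay apart for HSPA5 (2540 against 2090 to 2150, gap 0.871), LOXL1 (1370 against 1910 to 1980, 0.871), IGF1 (68.1 against 42.9 to 46.8, 0.847), ANKRD1 (926 against 493 to 512, 0.957), PRG4 (767 against 1070 to 1110, 0.882) and PODN (681 against 1030 to 1090, 0.869). It also lay apart for SOD3 (667 against 795 to 797, 0.987), MYLK (gap 0.967), ACTA2 (56800 against 45300 to 47200, 0.841), COX4I2 (128 against 26.3 to 40.5, 0.86), UBE2C (175 against 124 to 131, 0.865), ELN (21500 against 28100 to 29100, 0.873), NDUFA4L2 (1510 against 460 to 562, 0.903) and HSPB7 (477 against 346 to 364, 0.861). Replicate 1 lay apart for RPS24 (gap 0.862) and MSX2 (0.845), replicate 2 for CTH (0.897) and HERPUD1 (0.967), and replicate 3 for ISG15 (0.838), ISG20 (0.892), CFB (0.855), FKBP5 (0.868) and FLT1 (1.62 against 0 in the others, 1).

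For 15 named genes, the fitted changes over 21 days had opposite signs on plastic and on the media scaffold, each against day 0 on plastic, and limma called the difference between the media scaffold and plastic at day 21. This fitted log2 difference was 7.67 for the cathepsin CTSL, 3.51 for thrombospondin THBS1, −4.23 for DUSP6, 6.08 for COMP, 2.65 for the lysosomal LAMP2, 7.84 for TSPAN13, −8.83 for CRABP1 and 7.20 for C1QTNF3. It was 3.33 for IFIT5, 4.04 for the lipoprotein receptor VLDLR, 2.78 for KLF4, 2.93 for NQO1, −2.91 for the metallothionein MT1E, 2.604 for DNAJB9 and 2.69 for TP53INP1. For CTSL and COMP, with 0 reads on plastic at day 21, the fitted values depend on the added constant. Their levels at day 0, 1.173 and 3.16, lie below and barely above the 2.95 that 3 reads correspond to on plastic at day 21, so a fall on plastic is not shown for either. C1QTNF3 had 2 reads on plastic at day 21, so its fitted values depend on the added constant as well. Its ratio of the smart scaffold to plastic was 318 (counting interval 87.9 to 2630).

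The real grouping of the libraries was set against every other split of the same size. For the smart against the media scaffold 1 of 35 splits, the real one, gave as many genes (99, highest other 15). For the media scaffold against day 0 it was again 1 of 35 (3548, highest other 2139), which argues against chance for both. This share is the smallest that 35 splits can give and was not adjusted over the comparisons. An effect of a batch that followed the groups would pass as well. For day 3 against day 0 (1096, highest other 0) and the smart scaffold against day 0 (3354, highest other 0), 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05.

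Of the 99 genes called between the scaffolds, 91 were lower on the smart scaffold. With every library thinned to the same number of reads and genes called anew, 51 of the 53 called were lower, which argues against unequal depth. The median log2 change of the 91 genes was −1.53 with all reads and −1.52 after thinning. That decides little, because these genes had been chosen with the same reads. Leaving out 1 library at a time kept the median of the 91 genes between −1.60 and −1.51, which decides little because these genes had been chosen with all 7 libraries. With genes called anew in each of these fits the number called fell to between 53 and 62 in 4 of 7, and the lowest share of lower genes was 85.2% (52 of 61 without replicate 3 of the media scaffold, 95% exact interval 73.8% to 93% with genes taken as independent), so a part for single libraries stays open. The attached growth factors and a growth factor dose that differs between the 2 ways of supply stay open and were not tested.

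Between the media scaffold and plastic at day 21, 3879 genes were called. With the day 3 gradient as a covariate 77.1% of them were still called in the same direction, and with thinning 83.2% were. This argues against the gradient or unequal depth as the whole cause. The thinned reads are part of those that gave the calls, so chance losses in the plastic libraries were not tested. The gradient was defined from 3 of the libraries in the fit, so the covariate partly overfits those. The substrate, which the design names, stays open and was not tested apart from these.

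Of 4749 genes whose level was stable over the other groups, 68 were lower and 13 higher on plastic at day 21, among the lower ones CRLS1, ANAPC4, CACYBP and DPH6, with a median log2 difference of −2.55. With every library thinned to the same number of reads it was −2.57, so fewer reads alone did not lower these genes in the deeper libraries. That decides little about the depth of the plastic libraries, because these genes had been chosen with the same plastic reads. Chance losses in those libraries were not tested this way. These genes were also lower in the second day 3 library than in its mates (median −0.739, 65 of 68 genes, and 0 of 10000 random sets of matched genes as low, their lowest being −0.271), so a property shared by the plastic libraries of day 21 and that library, technical or biological, may contribute. With the gradient as a covariate the median difference between the media scaffold and plastic went from 2.62 to 2.19 and all 68 were still called, so the remainder stays open.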

How the results depend on the processing

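The gradient covariate, thinning to the fewest reads, and all alternatives for the scaffolds against day 0 on plastic were chosen only after the data were seen.

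Without the fold minimum, an adjusted p under 0.05 alone gave 3477 genes at day 3 against day 0, 7645 and 6814 on plastic at day 21 against day 0 and day 3, 258 between the scaffolds, 6966 and 7002 for the media and smart scaffold against plastic at day 21, and 6949 and 6655 for the media and smart scaffold against day 0. This follows from dropping the fold minimum. Between the scaffolds, where 99 genes were called, array weights gave 192 and thinning gave 53; the cause was not tested for the first, whose weights did not reach the convergence tolerance, and fewer reads were the construction of the second.

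Leaving out 1 library at a time gave 53 (without replicate 2 of the media scaffold) to 87 genes (without its replicate 4) between the scaffolds, with 61 without replicates 1 or 3 of the media scaffold and 62 without the second smart scaffold library. The other counts ran from 973 to 1308 at day 3, 4562 to 5244 and 3438 to 4249 on plastic at day 21 against day 0 and day 3, 3277 to 4304 and 3576 to 4518 for the media and smart scaffold against plastic, and 3441 to 3518 and 3258 to 3341 against day 0. Where plastic at day 21 was left with 1 library, it was assumed to vary like the other groups. Every other alternative tried kept these 8 counts within 1.5 times. The replicate numbers gave no pairing, since correlations over 20 pairs ran from −0.074 to 0.16, and blocking on them gave 78 genes between the scaffolds.

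Some values changed sign, and the cause was not tested. DES went to 0.38 (media scaffold against plastic) and 0.36 (smart) with the gradient covariate. COL1A1 between the scaffolds ran from −0.0335 without replicate 3 of the smart scaffold to 0.118 without replicate 2. The median of the myogenic regulators on plastic at day 21 against day 0 went to −0.161 at the same total per library and −0.00295 with the covariate, and ran from −0.0211 without the second day 21 library to 0.053 without the first. The skeletal muscle contractile median went to −0.322 with the covariate against day 0 and ran from −0.43 without the second to 0.626 without the first day 21 library, with −0.054 without replicate 3 of day 0. Against day 3 it went to −0.155 with the covariate and ran from −0.315 without the second day 21 library to 0.817 without the first day 3 library; without replicate 3 of day 3 the median was 0.207 while the direction of its test turned. Between the scaffolds it ran from −0.144 without the second media scaffold library to 0.0125 without the first smart scaffold library. Ribosomal proteins on plastic at day 21 against day 3 went to −0.204 with quantile normalization.

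Over all alternatives, the values of named genes kept direction and side of the threshold in 9591 cases, lost a call in 142, gained one in 3 and changed sign in 3. Gene lists did so in 1384, 137, 1 and 11 cases, and 90 of the 137 lost calls came from estimating the correlation between genes. Depth limited the genes with few reads most: 3 reads over the group correspond to 2.95 normalized reads on plastic at day 21 and 0.515 at day 0.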

Other observations

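The test of whether genes lower on the smart scaffold belong to those rising on plastic was chosen only after the result was seen.

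Lists outside the main account gave further values. Genes of the p53 response and senescence rose in 10 of 19 cases and fell in 1 on the smart scaffold against day 0 (camera adjusted p = 0.0043, and adjusted p = 0.028 with an estimated correlation), and rose in 6 and fell in 2 on the media scaffold (adjusted p = 0.0301, and adjusted p = 0.074 with an estimated correlation). Antigen presentation genes rose in 7 of 14 cases and fell in 2 on plastic at day 21 against day 0 (adjusted p = 0.0998), with BoLA higher, at 258.7 ± 79.1 on plastic at day 21 and 37.15 ± 5.11 at day 0, and the peptide transporter TAP1 lower, at 15.84 ± 2.97 and 169 ± 26.6. Of other cell type markers in this comparison, 2 of 6 endothelial genes rose and 2 fell (adjusted p = 0.612), with 1 lower when replicate 2 of plastic at day 21 was left out or the gradient was a covariate. Osteoblast genes rose in 2 of 6 cases and fell in 2 in the same comparison (adjusted p = 0.902, and 1 higher after rescaling to the same total), DLX3 being higher by 3.63 on the log2 scale and SPP1 lower, at −3.08. The VEGF receptor FLT1 had 584 reads at day 0 and 2 on each scaffold (ratios 224 and 132, counting intervals 61.7 to 1850 and 36.3 to 1090).

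Genes lower on the smart than on the media scaffold included several, such as SCARA5, SERPING1 and MFAP5, that rose over 21 days on plastic. Of the 91 lower genes, 73 (80.2%) were called higher on plastic at day 21 against day 0 and 5 lower, while 2247 of the 10869 other genes (20.7%) were called higher (Fisher exact p = 1.89e-33, odds ratio 15.6). Among 10000 random sets of matched genes the median share was 22% and the highest 38.5%. The 2 comparisons share no libraries. That they belong to a programme rising over 21 days may describe these genes (80.2%), but it was found and tested on the same data. Time and medium differ together in the plastic comparison, and growth factor supply was not tested.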
